A study of Mus musculus with 6 samples.

How the data were processed

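Messenger RNA of gastrocnemius, a mixed calf muscle made mostly of fast fibres, was sequenced from C57BL/6J mice aged 8 weeks. There were 3 wild-type (WT) libraries and 3 libraries from mice carrying a muscle-specific knock-out that the labels call MLL4SET-MKO. The name refers to the SET part of MLL4, the histone H3 lysine 4 methyltransferase encoded by Kmt2d. The labels call the 3 libraries of a group biological replicates. Muscle was flash frozen and RNA was extracted with Trizol, per the labels' protocols. The libraries were made with an NEBNext Ultra kit, per the labels' protocols, and whether strand was used in quantification is not given in the sources used here.

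The submitters' processing notes name bcl2fastq, FastQC 0.11.3, TopHat2 2.0.14 and Cufflinks 2.2.1, and the mouse build mm10 (GRCm38). The annotation release and the scaling between libraries are not given in the sources used here. The values come from 1 table in the layout of Cuffdiff, the comparison program of Cufflinks, per the file headers. For each gene or locus the authors gave an FPKM (fragments scaled to transcript length and to the mapped fragments of the library) of each group, so the 3 libraries of a group are summarised in 1 value. The authors' deposited table also holds a test statistic, used here as a score, with its p-value and its q-value. No column of single libraries entered the work, so no spread between mice could be computed and each group value is printed without one. Read depth is unknown, since FPKM carries no counts.

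The table held 25927 rows and 1 emptied line. The authors had marked 13347 rows as tested, 12569 as not tested and 11 as too deep to estimate. Those 11 rows are failed estimates. They cover the muscle genes Acta1, Atp2a1, Ckm, Myh4, Tnnt3, Ttn and Tpm1 and 4 genes that share their loci. Of these, 10 are listed at 0 in both groups, and Tpm1 is listed at 9004 FPKM in WT and 0 in MLL4SET-MKO. They entered no comparison and no total. No symbol was given for 1895 rows, of which 1068 were tested, and 368 rows carried several symbols. A column of log2 fold changes was not used, because a spreadsheet had turned part of it into error text. Ratios were computed again from the FPKM values.

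A gene was called when its q in the authors' deposited table was under 0.05 among the tested rows. Benjamini-Hochberg adjustment of the authors' deposited p-values over those rows gave their q-values within 0.0001. The smallest p in the authors' deposited table was 5e-05 (q = 0.000903), shared by 739 rows, so q does not rank the strongest calls. Changes are given as log2((MLL4SET-MKO FPKM + 1)/(WT FPKM + 1)) unless called a log2 ratio, which has no pseudocount. The pseudocount of 1 FPKM understates the change of low genes.

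The authors' p-values fitted a normal deviate of 1.74 times the test statistic (median over 11259 rows), close to 1.73, the square root of the 3 libraries per group. A standard error of each log2 ratio was worked back on that basis, and 95% intervals in the text use it. They rest on the authors' own model of the spread and not on values of single mice. The median standard error was 0.20 at a mean of 1 to 5 FPKM, 0.14 from 5 to 20, 0.13 from 20 to 100 and 0.13 from 100 FPKM upward, so lowly expressed genes were measured with less precision.

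Before the data were examined, 29 gene lists were fixed, 18 of genes and pathways and 11 of cell type markers. A member was measured when it was tested and its mean over both groups was at least 1 FPKM, and a member with 2 such rows counted as 2. Each list's median change was placed among 10000 random lists of the same size, matched on mean FPKM in 20 bins. This percentile describes these group values and is not a test across mice. Calls were counted over all rows tested and with Benjamini-Hochberg adjustment of the members' p-values over the list alone. The genes named follow a rule fixed at the same time. It takes Kmt2d, the 12 called genes with the largest increase and the 12 with the largest decrease (at least 1 FPKM in the higher group, no predicted or clone genes), and up to 4 called members of each list with the largest change. Where fewer than 2 members of a list were called, the 2 members of highest mean FPKM are added. This gave 95 genes, some of which are not reported here. Any other gene named was chosen after its values were seen.

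Coordinates are those of the authors' table on mm10, with starts counted from 1. Of 22642 rows whose symbol has 1 gene in GENCODE M21, 98.6% overlapped that gene. Where the authors' table gives several genes the same locus, their reads can overlap, and this is stated for the measured genes named.

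The calculation was tested on simulated data for MLL4SET-MKO against WT, with 13327 rows, the standard errors above and 200 changed genes, 50 of each size. It recovered 36.0% of genes with a log2 change of 0.50, 74.0% at 0.75, 90.0% at 1.00 and 100% at 2.00, and 5.66% of its calls were unchanged genes. Of 100 unchanged lists of 15 genes, 5 fell outside the middle 95% of random lists, and all 100 lists shifted by 0.50 did. The noise was drawn for each gene independently, from the same standard errors that formed the simulated p-values. The simulation therefore checks the arithmetic only. It cannot show which reading of the test statistic is right, or how lists of genes that vary together behave.

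The alternatives fixed before the data were examined were other q thresholds, a minimum fold, a minimum FPKM, another set of rows for the adjustment, 3 scalings, other pseudocounts, other minimum levels for list members and 10 bins. Reading the test statistic itself as a normal deviate, keeping only rows with a symbol, keeping only rows alone at their locus and removing the trend of change with exonic length and mean FPKM from the lists were added after the data were seen. Leaving out replicates, a replicate block and count models need values or counts of single libraries and were not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.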

Results

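Gene expression in gastrocnemius was compared between 3 WT libraries and 3 libraries of mice with a muscle-specific knock-out of the SET part of MLL4 (MLL4SET-MKO), all at 8 weeks of age. The SET domain is the catalytic part of this histone H3 lysine 4 methyltransferase, so the comparison asks which muscle transcripts differ when it is deleted in muscle. The values are the authors' FPKM of each group. At least 1 FPKM was reached by 11230 tested rows in WT and by 11292 in MLL4SET-MKO. The FPKM summed to 444208 in WT and 438161 in MLL4SET-MKO, without rows whose estimate failed. The 10 highest rows held 18.6% and 18.3% of these totals.

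Kmt2d, the targeted gene (chromosome 15, 98831669 to 98871205, minus strand, protein-coding), was lower in MLL4SET-MKO, at 5.65 FPKM against 8.77 in WT. The log2 ratio was -0.64 (95% interval -0.89 to -0.38), with q = 0.000903 in the authors' deposited table. A value over the whole gene does not show which part of the transcript was lost. Among 20 measured H3K4 methyltransferases and partner proteins, none was called over all rows tested or adjusted over the list alone. Their median change was 0.01, at the 82.0th percentile of matched random lists. The 2 highest, Dpy30 and the row shared by Hsd3b7, Orai3 and Setd1a, had log2 values of 0.01 and -0.05. With the test statistic read as a normal deviate, an alternative added after the data were seen, Kmt2d no longer passed (q = 0.13 after Benjamini-Hochberg adjustment).

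Of the 13347 tested rows, 1581 were called, 592 higher and 989 lower in MLL4SET-MKO. The median log2 ratio of called genes with at least 1 FPKM in both groups was 0.65 for the higher and -0.58 for the lower ones. Among genes with a symbol, ranked on the log2(FPKM + 1) scale, the largest decrease was that of Ppp1r1a, an inhibitor of protein phosphatase 1. This gene (chromosome 15, 103530279 to 103537992) fell from 28.1 to 0.809 FPKM (34.7-fold lower, log2 ratio -5.12, interval -5.63 to -4.60). It lies within 5 Mb of Kmt2d, as does the called gene Gpd1. In the window of 5 Mb either side of Kmt2d, 22 of 131 tested rows were called (16.8%, against 11.8% of all tested rows). A difference tied to the targeted stretch of chromosome was not separated from a response to the deletion. Padi2, which converts protein arginine to citrulline, fell from 51.8 to 4.72 FPKM at a locus shared with Gm13031, and the AMP-hydrolysing enzyme gene Nt5c1a from 20.04 to 2.76 FPKM. Agt, which encodes angiotensinogen, fell from 6.63 to 0.456 FPKM. The cytokine signalling inhibitor Cish fell from 35.2 to 7.65 FPKM and the nuclear receptor Nr4a3 from 21.4 to 4.43 FPKM. Efcab6 and Tmem52 were also among the 12 largest decreases, together with the slow fibre genes Tnnt1, Tnnc1, Myh7 and Myl2.

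On the same scale and among the same genes, the largest increase was that of Ostn (chromosome 16, 27307450 to 27370239), which encodes the secreted muscle and bone peptide osteocrin. It rose from 9.89 to 104.8 FPKM (10.6-fold higher, log2 ratio 3.41, interval 3.10 to 3.71), and its locus is shared with Uts2b. Pthlh, the gene of parathyroid hormone-related protein, rose from 1.09 to 8.63 FPKM. Slc40a1, the iron exporter ferroportin, rose from 15.6 to 54.9 FPKM, and the carbonic anhydrase gene Car2 from 5.88 to 19.7 FPKM. The kinase gene Sbk2 rose from 43.1 to 137.6 FPKM, and the metallothionein gene Mt3 changed by 1.71. Sntb1, which encodes a syntrophin of the dystrophin complex, rose from 4.16 to 16.0 FPKM. Tekt1, Igfn1, Prune2, Kcne1l and Pld5 completed the 12 largest increases, with changes from 1.51 (Pld5) to 2.45 (Tekt1). Without the pseudocount the ratio of Tekt1, which stood at 0.617 FPKM in WT, was the larger one (log2 ratio 3.66). All 24 of these genes carried q = 0.000903 in the authors' deposited table, the smallest it holds. The count of calls rested on how the p-values were formed: the test statistic read as a normal deviate called 415 rows, 165 higher and 250 lower. Of the 76 called genes among the 95 named, 41 passed on that reading.

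Slow fibre contractile genes fell together in MLL4SET-MKO. Of 17 measured members, 14 were called, all lower, over all rows tested and adjusted over the list alone, against 2.63 calls in an average random list. Their median change was -0.92, below all 10000 random lists. The slow troponin T gene Tnnt1 fell from 107 to 19.2 FPKM, a log2 ratio of -2.48 (interval -2.73 to -2.22). The slow troponin C gene Tnnc1 fell from 134 to 24.5 FPKM, and the slow myosin light chain Myl2 from 270.1 to 62.0 FPKM. Myh7, the slow myosin heavy chain (chromosome 14, 54968787 to 54994549), fell from 86.7 to 18.3 FPKM, a log2 ratio of -2.24 (interval -2.49 to -1.99), at a locus it shares with Mhrt and Mir208b. The 3 members that were not called were Pln, Myl6b and Sln, with log2 values of -0.37, 0.01 and 0.52, Pln at a locus shared with Cep85l and Gm19395.

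Fast fibre genes were called about as often as genes of random lists. Of 13 measured members, 1 was called higher and 1 lower, with the same counts adjusted over the list alone. An average random list had 1.98 calls, and 61.4% of random lists had as many. The median change was 0.05, at the 68.8th percentile, and neither call passed with the test statistic read as a normal deviate. The fast regulatory light chain Mylpf fell from 10773 to 6959 FPKM, and Myoz3, a Z-disc protein gene, rose from 83.5 to 106.7 FPKM. The fast myosin Myh1 stood at 692 FPKM in WT and 772 in MLL4SET-MKO (q = 0.64 in the authors' deposited table). Myh4, Tnnt3, Atp2a1 and Tpm1 had failed estimates, so Myh4, the main fast myosin of this muscle, was not measured. Of 5 genes of oxidative fast fibres, none was called over all rows or adjusted over the list alone, and the median change was 0.19 (93.2nd percentile). Myoglobin (Mb) stood at 1840 and 2299 FPKM and Cox6a2 at 1198 and 1117 FPKM, in WT and MLL4SET-MKO, both at loci shared with other genes.

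**Figure D1:**
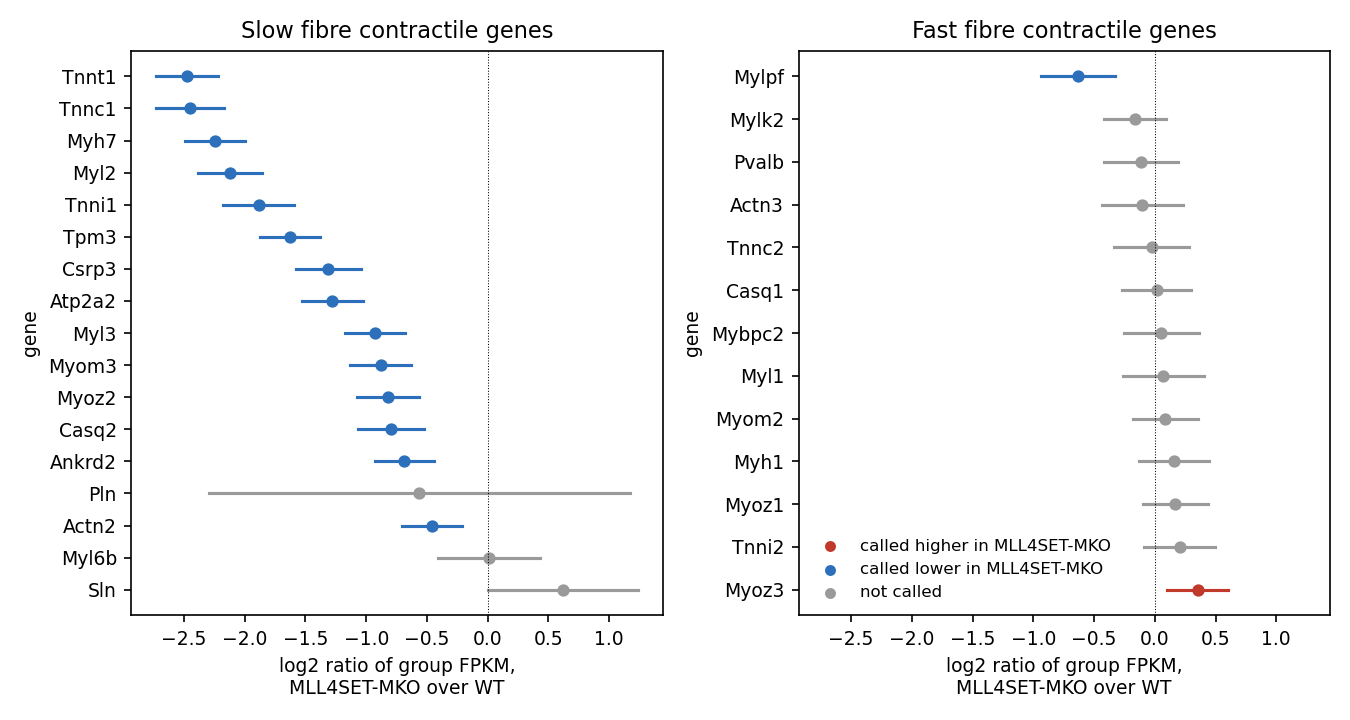
Log2 ratio of group FPKM, MLL4SET-MKO over WT (horizontal axis), for the measured slow fibre genes (left) and fast fibre genes (right). Points are the ratios of the authors' group values. Bars are 95% intervals that follow the authors' p-values, with a normal deviate of 1.74 times the test statistic. With the test statistic itself read as a normal deviate the bars would be wider. Of 17 slow fibre genes, 14 were called lower, and of 13 fast fibre genes, 1 in each direction.

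In the list of MEF2 transcription factors, calcineurin, NFAT, CaM kinase II and class II histone deacetylases, 20 members were measured. Of these, 6 were called lower and 1 higher, and 9 lower and 1 higher adjusted over the list alone, against 2.72 calls in an average random list. The median change was -0.24, at the 0.03rd percentile. The 2 MEF2 genes that were called went opposite ways: Mef2d fell from 74.8 to 45.1 FPKM, at a locus shared with 1700113A16Rik, and Mef2c rose from 147 to 231.6 FPKM. The kinase genes Camk2g and Camk2b fell by 0.63 and 0.41 on the log2 scale. No member of this list passed with the test statistic read as a normal deviate.

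Among 20 regulators of mitochondrial genes, 4 were called lower and none higher, and 5 lower adjusted over the list alone. An average random list had 2.55 calls, and 24.6% of random lists had as many. The median change was -0.12 (7.07th percentile), and no member passed with the test statistic read as a normal deviate. Ppargc1a, the coactivator PGC-1 alpha, fell from 12.3 to 7.65 FPKM and its target Perm1 from 89.4 to 59.5 FPKM. The fatty acid sensing receptors Ppard and Ppara changed by -0.50 and -0.34, Ppard at a locus shared with Scube3 and other genes. Of 15 circadian clock genes, 4 were called lower and none higher, 5 lower adjusted over the list alone. An average random list had 1.88 calls, and 10.7% of random lists had as many. The median change of the clock genes was -0.22 (0.45th percentile), and 1 passed on that reading. The called clock genes Hlf, Arntl and Cry2 changed by -0.54, -0.37 and -0.35, Cry2 at a locus shared with D930015M05Rik. The sampling time of day is not given in the sources used here.

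Genes of fatty acid use and of the respiratory chain had medians slightly above those of random lists. Of 27 genes of fatty acid uptake and oxidation, 4 were called higher and 2 lower, and 8 higher and 3 lower adjusted over the list alone. An average random list had 4.22 calls. Their median change was 0.19, above all random lists. Only Slc27a1, a lower gene, passed with the test statistic read as a normal deviate, so none of the higher calls did. Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose from 316 to 469 FPKM, and the electron transfer gene Etfb from 178 to 233.6 FPKM, at a locus shared with Mir7051. The uptake gene Slc27a1 fell from 41.7 to 22.4 FPKM, and the fatty acid binding protein Fabp3, which shares its locus with Zcchc17, from 429.6 to 298.6 FPKM. Of 72 respiratory chain and ATP synthase genes, 64 had a higher value in MLL4SET-MKO and the median change was 0.14, above all random lists. Only 2 of them, Atp5k and Ndufs6, were called, both higher, and 1 adjusted over the list alone, fewer than the 10.8 of an average random list, and neither passed on that reading. Across genes, which are not independent replicates, the Spearman correlation of log2 change with exonic length was -0.18, and these genes are short, with a median of 1675 bases. After the trend of change with length and mean FPKM was removed, an alternative added after the data were seen, the median was 0.14 (99.9th percentile) for the 69 respiratory chain genes with a length and 0.25, above all random lists, for 25 fatty acid genes. Of 21 tricarboxylic acid cycle genes, 2 were called lower and none higher, 3 lower adjusted over the list alone, with a median of 0.04 (63.9th percentile). An average random list had 3.21 calls, and no member passed on that reading. The 2 genes called lower over all rows were Idh3a, which fell from 372 to 248 FPKM, and Idh2, from 176 to 127 FPKM, at a locus shared with Zfp710 and Gm21057. Of 22 glycolysis and glycogen genes, 3 were called lower and 1 higher, 4 and 1 adjusted over the list alone, with a median of -0.06 (13.7th percentile), against 3.36 calls in an average random list. Of these calls, 2 passed on that reading. Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase, fell from 236.6 to 130.7 FPKM, and the muscle fructose bisphosphatase Fbp2 rose from 25.3 to 47.1 FPKM. Slc2a4, the insulin-regulated glucose transporter, changed by -0.38 and Phkg1 by -0.40, both at shared loci.

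Genes of developing and regenerating fibres were mostly higher, with a higher value in 8 of 11 measured members. Of the 11, 6 were called higher and 1 lower, 7 and 1 adjusted over the list alone. An average random list had 1.39 calls. The median change was 0.48, above all random lists, and 4 higher members passed with the test statistic read as a normal deviate. The member called lower was Myf5, which fell from 1.46 to 0.789 FPKM and did not pass on that reading. Myod1 and the row of H19 and Mir675, not called, changed by -0.14 and -0.18. The neonatal myosin Myh8 rose from 0.495 to 2.35 FPKM, the stretch-responsive gene Ankrd1 from 2.45 to 7.42 FPKM and Igf2, which shares its locus with Igf2os and Mir483, from 8.83 to 17.0 FPKM. Cardiac actin, Actc1, rose from 552 to 1488 FPKM, which is uncertain because the estimate of its near-identical paralog Acta1 failed. Of 12 genes of denervation and the neuromuscular junction, 2 were called higher and 3 lower, over all rows and adjusted over the list alone (median -0.08, 25.1st percentile). That is 5 calls against 1.36 in an average random list (0.68% had as many), of which 2 passed on that reading. Myog, which rises in denervated muscle, fell from 5.34 to 2.16 FPKM and Dok7, a synapse adaptor, from 9.22 to 5.13 FPKM. Gadd45a, at a locus shared with E230016M11Rik, rose from 11.9 to 22.7 FPKM, and Chrnb1 changed by 0.40.

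Of 18 atrophy genes, 3 were called higher and 4 lower, 4 and 5 adjusted over the list alone, with a median of -0.04 (46.5th percentile). That is 7 calls, in both directions, against 2.49 in an average random list (0.64% had as many), and 2 passed with the test statistic read as a normal deviate. The transcription factor Foxo1 fell from 21.8 to 12.3 FPKM and the ubiquitin ligase Trim63 from 148.7 to 97.1 FPKM. Eda2r rose from 5.46 to 10.2 FPKM, and the autophagy receptor Sqstm1 from 269.7 to 374 FPKM. Of 12 integrated stress response genes, 3 were called higher and 2 lower, both over all rows and adjusted over the list alone (median 0.03, 75.9th percentile), against 1.49 calls in an average random list (0.99% had as many). On that reading 2 passed. Mthfd2 rose from 2.89 to 7.05 FPKM and Chac1 fell from 68.1 to 38.7 FPKM. Atf3 changed by 0.44 and Atf5, at a locus shared with Nup62 and other genes, by -0.74. None of 11 heat shock genes was called over all rows or adjusted over the list alone (median 0.09, 90.1st percentile), and the highest, Hspa8 and Hspb6, had log2 values of 0.09 and 0.14, Hspb6 at a locus shared with Proser3 and Lin37. Of 10 immediate early genes, 2 were called higher and 1 lower, 3 and 2 adjusted over the list alone (median 0.05, 87.7th percentile). An average random list had 1.21 calls (10.4% had as many), and 2 members passed on that reading. Besides Nr4a3, the genes called over all rows were Jun, which rose from 32.6 to 47.7 FPKM, and Egr1, from 2.79 to 6.35 FPKM. Nr4a3 and Egr1 were the ones that passed, and Jun did not.

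Macrophage markers were higher in MLL4SET-MKO. All 10 had a higher value, 5 were called over all rows and 9 adjusted over the list alone, against 1.21 calls in an average random list. The median change was 0.45, above all random lists. The lysozyme gene Lyz2 rose from 43.2 to 77.3 FPKM (log2 ratio 0.84, interval 0.57 to 1.11), and the complement genes C1qa, C1qb and C1qc rose by 0.53, 0.57 and 0.47. With the test statistic read as a normal deviate, 1 member passed. No marker on the neutrophil and lymphocyte lists reached the level for measurement. Outside the lists, and picked after their values were seen, 2 unnamed rows overlapping Ighm, an immunoglobulin gene of B cells (chromosome 12, 113418558 to 113424322), were called lower. They fell from 5.82 to 0.441 FPKM and from 9.45 to 0.991 FPKM. None was called, over all rows or adjusted over the list alone, among 10 endothelial markers (median -0.10, 26.4th percentile), 10 fibroblast markers (0.09, 92.6th), 6 Schwann cell markers (-0.02, 54.7th), 6 adipocyte markers (0.09, 89.5th) and 5 erythroid rows (-0.05, 44.3rd). Among the highest of these were Egfl7 and Cdh5, Dcn and Col1a2, Pmp22, Fabp4 and Cfd, and the globin rows, with log2 values between -0.29 (Egfl7) and 0.40 (Cfd, at a locus shared with many genes). Egfl7 shares its locus with Agpat2, Cdh5 with Gm29682 and Pmp22 with Cdrt4, Tekt3 and others.

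Among 7 smooth muscle and pericyte markers, Abcc9 was called lower, over all rows and adjusted over the list alone (median -0.13, 17.2nd percentile), a call that did not pass with the test statistic read as a normal deviate. It is a potassium channel subunit gene that muscle fibres also express, and fell from 79.1 to 55.9 FPKM at a locus shared with 5330439B14Rik. Of 3 measured satellite cell markers, Chodl was called lower over all rows, and all 3 were called lower adjusted over the list alone (median -0.32, 3.42nd percentile), and none passed on that reading. Among 7 tendon markers, Thbs4 was called higher, rising from 40.3 to 69.0 FPKM, and 2 were called higher adjusted over the list alone (median 0.03, 82.4th percentile). In all, 7 of 26 lists lay outside the middle 95% of their random lists, against 1.30 expected for lists of genes drawn at random. Members of a list can vary together between mice, so the excess over 1.30 is not a test of genotype. After the trend with length and level was removed, 9 of 25 lists lay outside, with fibroblast and satellite cell markers added.

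**Figure D2:**
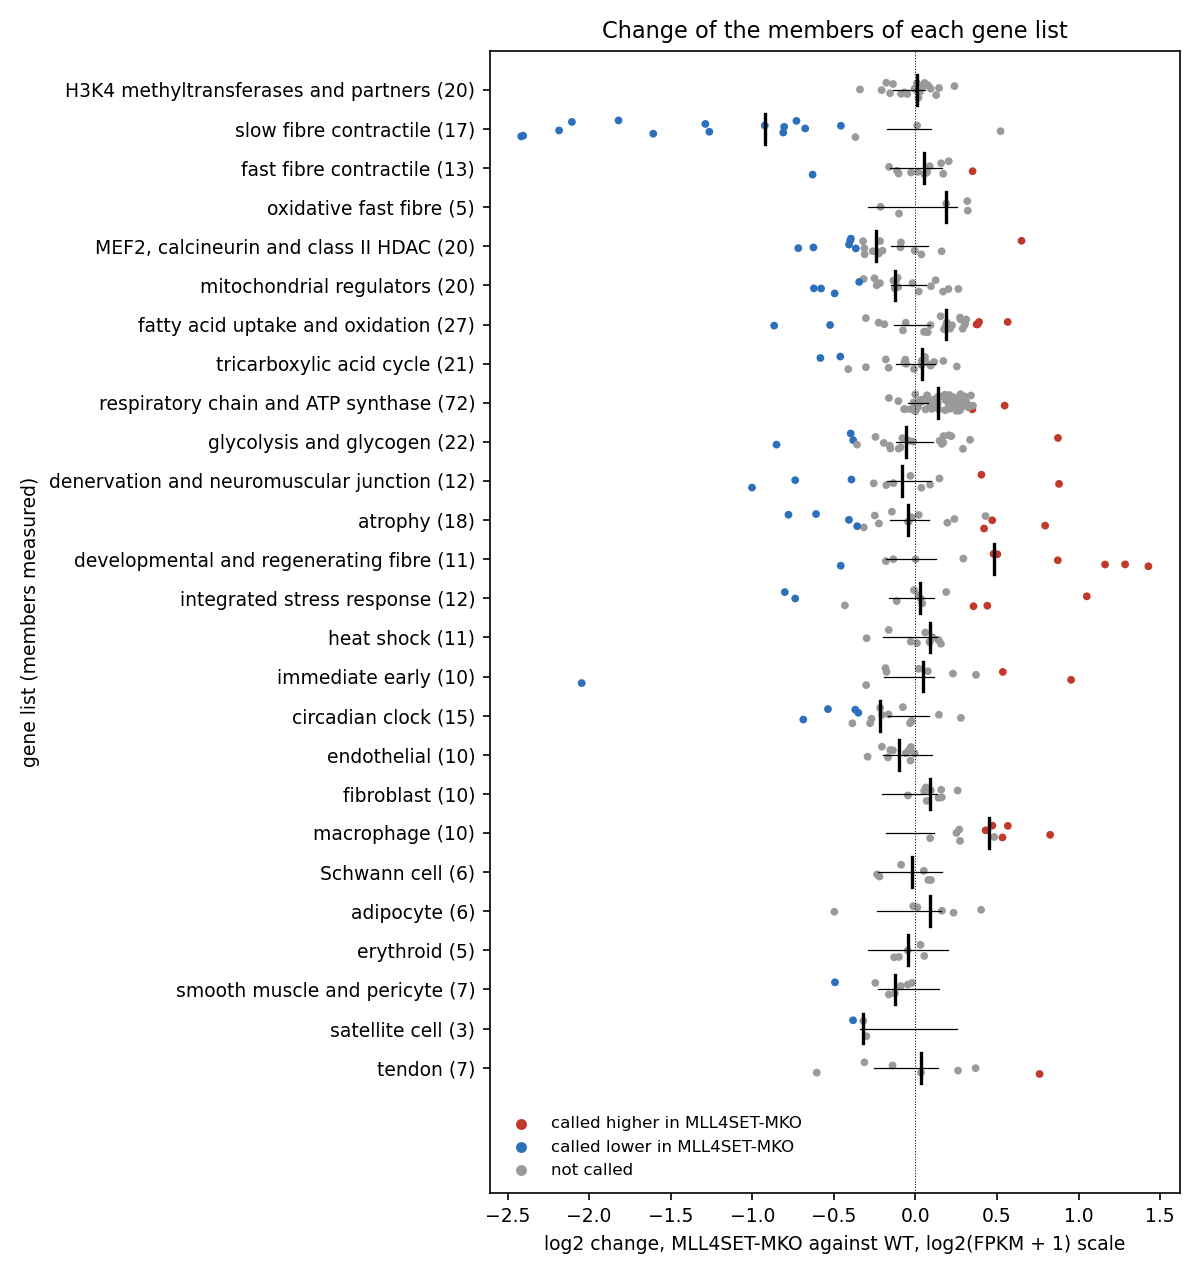
Log2 change of each measured list member, MLL4SET-MKO against WT on the log2(FPKM + 1) scale (horizontal axis), by gene list with the number of members. Points are genes coloured by the call, thick bars the list medians and thin lines the middle 95% of medians of 10000 matched random lists; the medians were -0.92 for slow fibre, 0.48 for developmental and 0.45 for macrophage genes.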

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

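Reading the test statistic as a normal deviate, keeping only rows with a symbol, keeping only rows alone at their locus and removing the trend with length and level from the lists were chosen after the data were seen. The count of 1581 called genes (592 higher) moved to 1048 (374 higher) at q under 0.01. It moved to 621 (241 higher, 380 lower) with at least 1.5-fold and to 186 (69 higher, 117 lower) with at least 2-fold. Stricter limits keep fewer genes. Both folds were taken on the log2(FPKM + 1) scale. Low genes with a larger plain ratio, such as Egr1 (2.27-fold, change 0.95), therefore fell under the 2-fold limit. Reading the test statistic as a normal deviate gave 415 (165 higher, 250 lower), of which 407 were among the 1581. The normal deviate behind each gene is then 1.74 times smaller. Only the 13327 of 13347 tested rows with a finite statistic could pass on this reading. The median size of the log2 ratio was 1.27 for called genes that passed and 0.57 for those that did not. On that reading the change of Kmt2d, -0.56, lost its call (q = 0.13), as did 34 of the other 94 named genes, while 13 of the 14 slow fibre genes passed. Under all other settings run, the count stayed between 1319 and 2033. The 3 scalings moved MLL4SET-MKO by log2 0.04 at most. The smallest called log2 ratio was 0.34 in size among rows with at least 1 FPKM in both groups, and no called row changed direction. Calls were not made again after scaling, so these 3 settings could not change the count and do not show whether marginal calls would hold. Kmt2d stayed between -0.64 and -0.52, the slow fibre median between -1.26 and -0.87, and 7 or 8 lists lay outside the middle 95% of random lists, or 9 of 25 after the trend with length and level was removed. The median of mitochondrial regulators lay there only with members of at least 5 FPKM (-0.22), that of satellite cell markers only with a pseudocount or a minimum level of 0.1 FPKM (-0.44 and -0.35) or after the trend was removed (-0.30), that of fibroblast markers only after the trend was removed (0.20), and that of tendon markers only for members alone at their locus (0.26). No paired analysis was possible because the table gives 1 value per group. For the same reason leaving out replicates, other splits of the mice and DESeq2 were not run, so no call could be tried without a given mouse.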

Other observations

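The tests in this part were chosen after the data were seen, the test of gene length and level on the slow fibre genes included, although the bound for that test was written before its own outcome was seen. Across 119 families of gene symbols with at least 10 measured members, those named Pde (phosphodiesterases), Slc (solute carriers) and Dusp (dual-specificity phosphatases) had the lowest shares of random lists with as many calls. Of 14 Pde genes, 8 were called, 6 lower and 2 higher, against 1.66 in an average random list, and none of 10000 random lists reached that number. Pde4a, at a locus shared with Mir7667, fell from 21.2 to 11.4 FPKM and Pde2a, at one shared with Mir139, from 14.2 to 7.55 FPKM, the only 2 calls that passed with the test statistic read as a normal deviate. Of 176 Slc genes, 36 were called, 26 lower and 10 higher, against 20.4 (0.04% of random lists had as many), and 12 passed on that reading. Slc37a4, which transports glucose-6-phosphate, fell from 97.9 to 38.7 FPKM at a locus shared with Mir7085. Of 19 Dusp genes, 8 were called, 5 lower and 3 higher, against 2.42 (0.11% of random lists had as many). Dusp18 fell from 9.60 to 4.07 FPKM and Dusp26 rose from 19.2 to 33.2 FPKM, and 4 of the 8 passed on that reading.

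Called members of the fixed lists that lay under the level for measurement included the satellite cell marker Fgfr4, which fell from 1.29 to 0.200 FPKM, the fusion gene Tmem8c, which rose from 0.123 to 1.07 FPKM, and the embryonic myosin Myh3, which rose from 0.402 to 1.23 FPKM at a locus shared with Mir6923.

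The fall of slow fibre genes was weighed against technical sources. Scaling between the groups would shift all genes alike. The median log2 ratio of the 10992 tested rows with at least 1 FPKM in both groups was -0.037. The submitters' scaling is not given, and one that centres the median would itself bring this value near 0. After the trend of change with exonic length and mean FPKM was removed, the median of the 17 slow fibre genes was still -0.92, below all random lists. A smaller share of neighbouring slow muscle in the dissected tissue may also lower these genes and cannot be told apart from a change within fibres. The interval of Myh2, a myosin that slow mixed muscle also holds, spans 0 (log2 ratio -0.21, interval -0.49 to 0.06). The 5 oxidative fast fibre genes, Myh2 included, went both ways, 3 higher and 2 lower, with none called. An effect of the genotype stays open as well.

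The rise of macrophage markers was weighed in the same way. A lower share of muscle fibres would raise the markers of every other cell type, whereas the median of endothelial markers was -0.10 (0.030 after the trend with length and level was removed, against 0.46 for macrophage markers). The lowest macrophage marker, at 0.09, lay above the highest endothelial one, at -0.01, but fibroblast markers were not separate: 9 of 10 had a higher value, Col3a1 a log2 value of 0.26, and their median of 0.09 became 0.20 (98.6th percentile) after the trend was removed. More blood would raise the globin rows by about the macrophage median log2 ratio of 0.50, whereas the mean of 4 globin rows was -0.023, with an upper 95% bound, errors taken as fully shared, of 0.26 from the p-values and 0.47 with the test statistic read as a normal deviate. The mean was chosen after the single rows had been seen, of which 3 had bounds under 0.50 on both readings and Hbb-b2 reached 0.61 on the second. A larger number of macrophages and a change within them remain candidate explanations that group values of whole muscle do not separate.

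A stretch of 309.1 kb on chromosome 6 (66080773 to 66389909, mm10) held 27 unnamed segments, all with a higher value in MLL4SET-MKO. GENCODE M21 places 2 pseudogenes there, Gm44289 and Gm31520, and no protein-coding gene. The segments are listed at 0 in WT in 18 cases and reach at most 0.0542 FPKM there, against 0.205 to 19.7 FPKM in MLL4SET-MKO. The highest, from 66368815 to 66389909, stood at 0.0406 FPKM in WT and 19.7 in MLL4SET-MKO, and 9 of 16 tested segments were called. Background from genomic DNA or unspliced RNA would raise unnamed loci elsewhere, whereas the median change of the other 1052 tested unnamed rows was 0.014. The lowest of the region's segments, at 0.27, was not among the tested rows. The region was picked after its values were seen, so its distance from that median carries no weight of its own. An inserted or rearranged piece of DNA in the mutant line is a hypothesis that stays open: WT reached 10% of the MLL4SET-MKO level in 0 of the 27 segments, and deciding it needs reads that join the region to other DNA, not analysed here.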
